A study of Mus musculus with 8 samples.

How the data were processed

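RNA was measured in 8 libraries of cultured adult mouse (C57BL/6) cardiomyocytes, 4 transfected with a control siRNA (siN) and 4 with an siRNA against Hoxa5 (siHoxa5). Per the labels' protocols, phenylephrine was added 24 h after transfection at 100 µM for 24 h in both groups, mRNA was selected with poly-T beads, and TruSeq libraries were sequenced on a NovaSeq. Groups and replicate numbers were taken from the sample titles. The labels do not say whether the 4 repeats of a group came from separate animals or cultures, so p-values measure the spread between these libraries.

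The deposited files hold estimated counts per gene symbol, not normalized by the authors: whole numbers, except 4 rows with values that end in 0.5. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.6.1b, HTSeq and R 3.5.3 were used with the mm10 build. The annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. The kit named does not mark strand, so reads of overlapping and antisense genes cannot be told apart. The 8 columns of the series table were identical to the libraries' own files.

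The gene symbols in the files are spelled as human genes are. Of 33514 rows, 19 were spelled exactly as a GENCODE M21 mouse symbol and 16245 matched one once case was ignored, while 16645 had no mouse namesake even with RefSeq synonyms. Of those 16645 rows, 315 had a count. Symbols are printed as the files give them, and mouse gene lists were matched to them by name. Library totals ranged from 560190 to 658192 counts, and 7926 rows had at least 1 count in any library. No row was blank or a summary line. In 27 rows the symbol had been turned into a calendar date. These rows held 0.320% of the counts, and 2 of the names occurred a second time; they were kept as separate rows. Because the totals are low, genes with few counts were measured imprecisely: the median standard error of a log2 fold change was 0.17. Intervals and limits given for counts cover counting error only.

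Values were rounded to whole counts and tested with edgeR 4.0.16 (quasi-likelihood fit, robust, on limma 3.58.1 and R 4.3.3) after TMM scaling and the filterByExpr filter (minimum count 10, minimum total 15), with Benjamini-Hochberg adjustment and a threshold of 0.05. All 8 libraries entered the fit, with the group as the only term. The filter kept 3020 genes, which held 98.6% of the counts. The common biological coefficient of variation was 6.10%. CPM values use TMM-scaled library sizes. Adjusted p-values of single genes given in the text are from this edgeR test unless another tool is named.

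Fixed gene lists, 35 in all, were written before the data were examined. Lists with at least 5 tested members, 17 of the 35, were tested with limma's camera (two-sided, preset inter-gene correlation 0.01, log2 CPM with a prior count of 2), and also with an estimated correlation and with fry. The lists tested were hypertrophy markers, hypertrophic signalling, cardiac transcription factors, immediate-early and MAPK-responsive genes, sarcomere and Z-disc, calcium handling and ion channels, glycolysis, nuclear oxidative phosphorylation, extracellular matrix and fibrosis, cardiomyocyte dedifferentiation and cytoskeleton, p53 targets, the unfolded protein and integrated stress response, mTORC1, autophagy and lysosome, ubiquitin-proteasome and atrophy, cytosolic ribosomal proteins, and fibroblast markers. Shares of counts in 10 lists of markers of other cell types and 4 library properties were compared by a two-sided exact permutation test over the 70 assignments of 8 libraries to 4 and 4, adjusted by the Benjamini-Hochberg method within each family.

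The genes named in the text follow a rule set before the data were examined: Hoxa5 and Hox genes that pass the filter; the 12 largest increases and the 12 largest decreases past the threshold with a mean of at least 5 CPM and no overlap between groups (leaving out symbols of Gm plus digits and those that end in Rik or -ps); up to 4 members with the smallest p in each list; the 5 smallest p overall; and the 3 genes with the highest mean CPM. The 9 abundant or stress-marking heart genes at 0, CKM, ACTA1, TNNT2 and those of the closing part fall outside this rule. A gene named outside this rule was chosen after its values were seen. Some genes that the rule selects are not reported here.

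The edgeR and camera steps were tested on simulated counts for this comparison, with 200 genes changed by known folds (2954 genes passed the filter). The test recovered 25.4% of genes changed 1.25-fold, 61.5% of those changed 1.5-fold and 85.9% of those changed 2-fold. Of 114 calls, 2 were false. Camera called the 1 raised list and 0 of 24 unchanged lists. The simulated genes were drawn independently, so false calls of lists with correlated genes were not tested. Both simulated groups had the same dispersion per gene, so false calls where siHoxa5 libraries vary more than siN libraries were not tested either. In the real lists the estimated correlation reached 0.272, for cytosolic ribosomal protein genes. Pairs of libraries of 1 group differed by more than counting noise in every case (chi-square per degree of freedom 1.35 to 1.50 among siN and 1.46 to 2.42 among siHoxa5 libraries, over genes with at least 10 counts in the pair), so no library was treated as deposited more than once.

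Alternatives covered DESeq2 size factors, no scaling beyond totals, other count filters, a replicate block, each library left out in turn, removal of mitochondrially encoded genes, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, and stricter thresholds. Alternatives added after seeing the data left out siHoxa5 libraries 2 and 4, removed the myosin heavy chain genes, thinned each library to the lowest total, or removed each library's trend on transcript length and GC content (from the longest GENCODE M21 transcript, known for 98.4% of tested genes). Exact tests, tables and figures were made with Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3.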

Results

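The data are RNA-seq counts from adult mouse cardiomyocytes, the contractile cells of the heart, kept in culture, transfected with siRNA and then given phenylephrine, an agonist of alpha1-adrenergic receptors that is widely used to induce hypertrophic growth of cardiomyocytes. All 8 libraries received phenylephrine at 100 µM for 24 h; 4 carried a control siRNA (siN) and 4 an siRNA against Hoxa5 (siHoxa5), a homeobox transcription factor. The single comparison, siHoxa5 against siN, asks which transcripts differ when Hoxa5 is targeted in phenylephrine-treated cells. No libraries without phenylephrine were used here, so the response to phenylephrine itself was not measured.

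Each siN library held 635824 to 658192 counts (mean 646832 ± 10946, SD, n = 4), and each siHoxa5 library 560190 to 619942 (592601 ± 29616, SD, n = 4). Between 5312 and 5763 genes had a count in a library. The symbols in the files are spelled as human genes, and 9 genes that adult mouse heart muscle expresses abundantly or that mark its stress (MB, FABP3, MYL2, MYL3, TNNI3, PLN, NPPA, NPPB and CD36) had 0 counts in all 8 libraries. These 9 were chosen after the values were seen, for being at 0; CKM, the muscle creatine kinase looked at with them, had 11 counts in all. The natriuretic peptide genes NPPA and NPPB, classical markers of hypertrophy, therefore could not be compared. Fold changes compare a gene with itself between groups; how reads shared between members of a family, such as the myosin heavy chains, were counted is not given in the sources used here.

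Hoxa5, the siRNA target, lies on chromosome 6 of the mouse genome (GRCm38, 52201754 to 52204587, minus strand, GENCODE M21 gene ENSMUSG00000038253.6), in the Hoxa cluster. HOXA5 was close to the detection limit in both groups. The siN libraries 1 to 4 had 2, 0, 3 and 3 counts (3.08, 0, 4.72 and 4.60 CPM), and the siHoxa5 libraries 1, 3, 4 and 1 (1.63, 5.46, 6.52 and 1.82 CPM). A library needed 3 counts, 4.60 to 5.46 CPM, to exceed what a count of 0 allows. Summed over each group, 8 counts in siN stood against 9 in siHoxa5, a ratio of rates of 1.23 with an exact 95% interval of 0.421 to 3.66. A lower level of HOXA5 in the siHoxa5 libraries was not detectable at this depth, and a fall to a level under 0.421 of that in siN lies outside the interval for counting error. This holds only if the few reads in the row come from Hoxa5, which the counts cannot show. The gene did not pass the expression filter. Fitted without the filter, its log2 fold change was 0.31 (SE 0.85, edgeR adjusted p = 0.887), and the exact permutation test of the CPM gave p = 0.657 (two-sided, n = 4 and 4). Of the 39 Hox genes listed, 17 had any count, with 62 counts in all and no more than 4 in any library, and none passed the filter. The counts thus cannot tell a moderate knockdown from none, and directions below are those of libraries labelled siHoxa5 against those labelled siN.

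Of the 5 genes with the smallest p, MYH6, FHL1 and STC1 were higher and MYBL1 and MSN lower in the siHoxa5 libraries. MYH6, the alpha myosin heavy chain of adult mouse ventricle, rose from 21752 ± 839 to 30432 ± 1417 CPM (SD, n = 4 each), a log2 fold change of 0.48 (SE 0.04, edgeR adjusted p = 1.15e-19). FHL1, a LIM-domain protein of the sarcomere, rose from 3904 ± 129 to 5923 ± 653 CPM. STC1, which encodes the secreted glycoprotein stanniocalcin 1, went from 102 ± 2.99 to 248 ± 24.8 CPM, and PPARGC1A, the coactivator PGC-1alpha that drives mitochondrial gene programmes, from 109.6 ± 14.1 to 254 ± 41.0 CPM (log2 fold change 1.21, SE 0.13). The strongest evidence for a decrease was for MYBL1, a transcription factor of the MYB family, which went from 579.8 ± 23.4 to 284 ± 43.2 CPM (log2 fold change -1.02, SE 0.09, adjusted p = 9.90e-20), and for MSN, which encodes moesin, a linker of actin to the membrane, at 1865 ± 67.2 against 1215 ± 94.6 CPM.

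**Figure D1:**
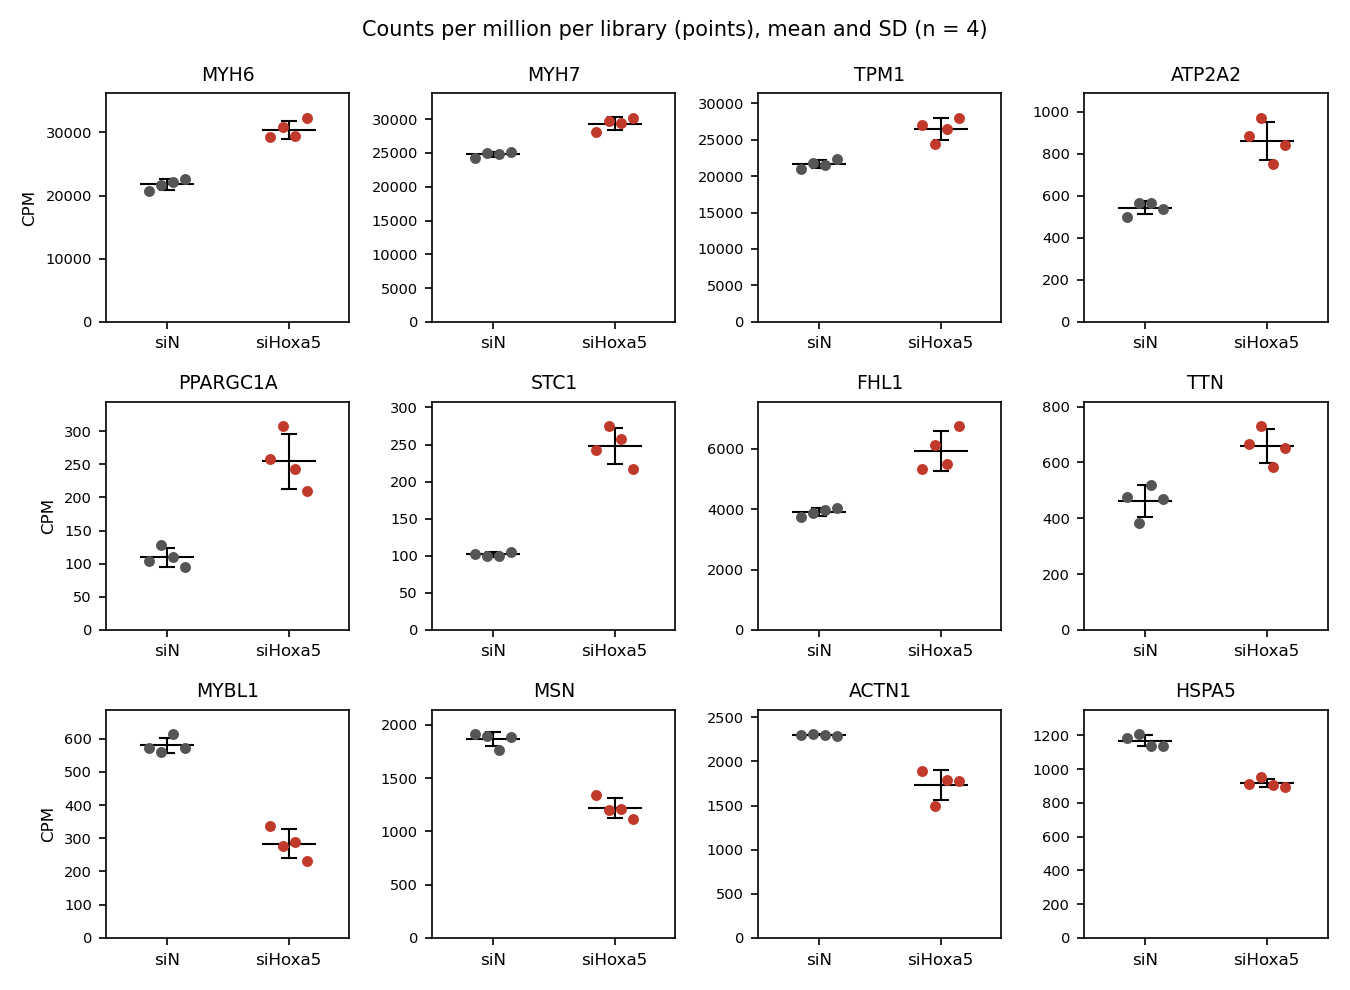
CPM (counts scaled to library size) of 12 genes in each library. Points are the 4 libraries of each group, horizontal bars the mean and error bars the SD; in all 12 panels the siN and siHoxa5 points do not overlap, with MYBL1 at 560 to 614 CPM in siN and 233 to 338 CPM in siHoxa5.

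In all, 215 of 3020 tested genes passed the threshold, 113 higher and 102 lower in the siHoxa5 libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median absolute log2 fold change of the 215 was 0.40, and 10 genes rose and 5 fell by 2-fold or more. The 2 groups' CPM values did not overlap for 177 of the 215, and for 361 of all 3020 tested genes, where chance gives 2.86% of genes. DESeq2 called 112 genes, 111 of them among the 215, and 96 of the 215 were called whichever library was left out. Without siHoxa5 libraries 2 and 4, which lay apart from the others on the first principal component, 143 genes were called, 118 of them among the 215.

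**Figure D2:**
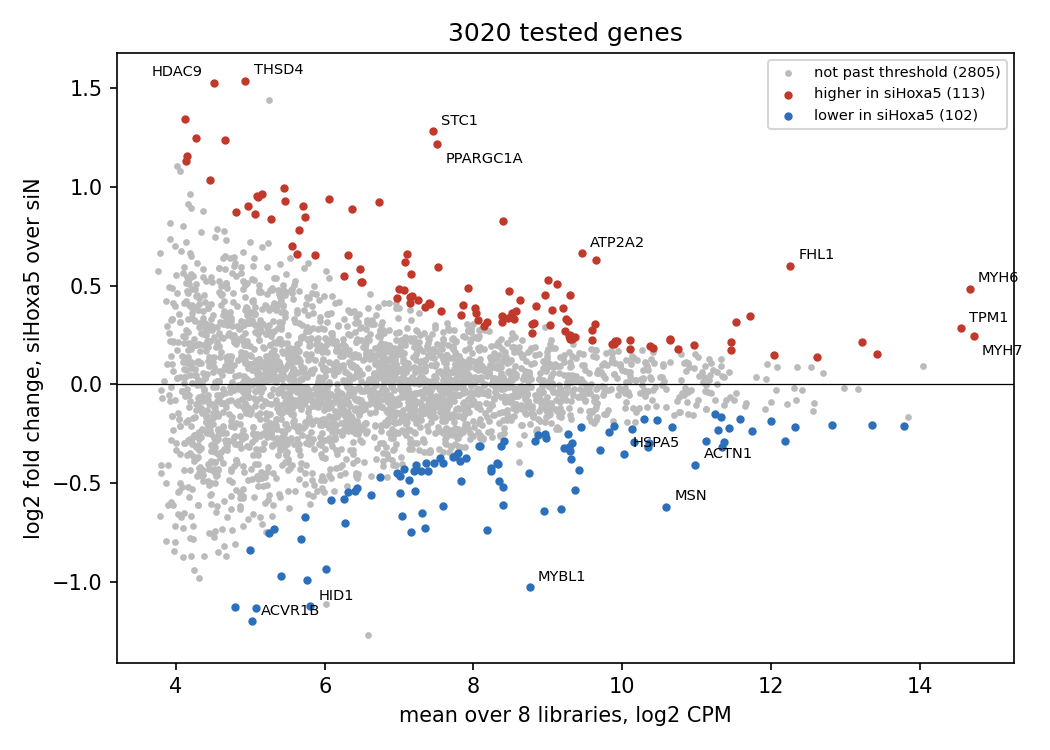
Log2 fold change (siHoxa5 over siN, vertical axis) against mean expression (log2 CPM, horizontal axis) of the 3020 tested genes. Red points are the 113 genes higher and blue points the 102 genes lower in siHoxa5 at adjusted p under 0.05; the highly expressed MYH6, MYH7 and TPM1 all lie above 0.

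Besides STC1 and PPARGC1A, described above, the largest increases came from genes of modest expression. THSD4 rose from 15.6 ± 3.74 to 45.4 ± 9.32 CPM (log2 fold change 1.54, SE 0.29) and HDAC9, a class IIa histone deacetylase that binds MEF2 factors, from 11.7 ± 2.57 to 34.1 ± 6.15 CPM (1.53, SE 0.34). RGMA, a coreceptor for bone morphogenetic proteins, rose by 1.34 on the log2 scale, C4orf54 from 11.3 ± 4.98 to 27.1 ± 8.60 CPM, CASQ1, the calsequestrin of skeletal muscle, by 1.23 on the log2 scale, KCNN2, a calcium-activated potassium channel, by 1.16, FSD1L by 1.13, PFKM, the muscle phosphofructokinase, by 1.03, KLHL41, a protein of the skeletal muscle sarcomere, by 0.96 and AUTS2 by 0.95. Besides MYBL1, described above, the largest decreases were in ACVR1B, a type I receptor for activin (45.6 ± 3.42 to 19.6 ± 5.84 CPM, log2 fold change -1.20, SE 0.28), the row AL133387.3 (-1.13), LTA4H, the leukotriene A4 hydrolase (-1.12), HID1 (-1.12), SYT11, a synaptotagmin (-0.99), RNF149 (-0.97), JAG2, a ligand of Notch receptors (-0.94), BMP2, a bone morphogenetic protein (-0.84), PKP1, a plakophilin (-0.78), PDIA5, a protein disulfide isomerase (-0.75), and ABHD2 (-0.74). Without siHoxa5 libraries 2 and 4 the calls of RGMA, C4orf54, CASQ1, KCNN2, FSD1L, PFKM, ACVR1B, RNF149, BMP2, PKP1 and PDIA5 were lost, and CASQ1 fell to 0.62, while C4orf54 (1.24) and BMP2 (-0.94) had changes about as large as, or larger than, with all libraries. Of these genes, all but ACVR1B and RNF149 also lost their calls under some setting chosen beforehand. AUTS2 lost its call with DESeq2 and without siHoxa5 library 3 or siN library 1, KLHL41 with DESeq2 and without siHoxa5 library 1 or siN library 3, and LTA4H with DESeq2 and without siN library 2. Of the 54 named genes past the threshold, 31 were called under every setting chosen beforehand and 26 also under those added later. The stricter thresholds were not applied in these counts.

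Sarcomere and Z-disc genes rose as a group (median log2 fold change 0.27 over 14 tested members, camera adjusted p = 0.00859; adjusted p = 0.201 with an estimated correlation). Of the 14, 5 rose, 1 fell and 8 did not pass; adjusted over the list alone 6 rose and 1 fell. Besides MYH6, the risers were TPM1, the alpha tropomyosin (21674 ± 559 to 26441 ± 1488 CPM, log2 fold change 0.29), TTN, the giant spring protein titin (0.51), ACTN2, the alpha-actinin of the Z-disc (0.31), and MYH7, the beta myosin heavy chain (24770 ± 407 to 29350 ± 921 CPM, 0.24). TNNT2, cardiac troponin T, fell by 0.44; it is named outside the rule, as the only member that fell. MYH7, MYH6 and TPM1 were the 3 most highly expressed genes in the files. MYH7 and MYH6 are close in sequence, and how their reads were divided is uncertain. With each library's trend on transcript length and GC content removed, TTN moved to 0.20 and no longer passed.

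Hypertrophy marker genes were also higher as a group (10 tested, median 0.14, camera adjusted p = 0.0421; adjusted p = 0.282 with an estimated correlation), although the list shares MYH6, MYH7 and ATP2A2 with others. Of the 10, 5 rose, none fell and 5 did not pass; adjusted over the list alone 5 rose and 1 fell. FHL1 rose by 0.60, and ACTA1, the skeletal alpha-actin that is re-expressed in hypertrophy and is named outside the rule, by 0.22. The members that rose include both a gene usually lower in hypertrophied mouse hearts (MYH6) and genes usually higher (MYH7, ACTA1). How reads shared between MYH6 and MYH7, or between actin genes, were counted is not known. These rises therefore need not be those of separate genes. Without the myosin heavy chain genes the list no longer passed (median 0.01).

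Calcium handling and ion channel genes had a median of 0.28 over 12 tested members (camera adjusted p = 0.0178; adjusted p = 0.201 with an estimated correlation). Of these, 3 rose, none fell and 9 did not pass; adjusted over the list alone 6 rose and 1 fell. ATP2A2, the calcium pump SERCA2 of the sarcoplasmic reticulum, rose from 544 ± 32.0 to 862 ± 91.5 CPM (log2 fold change 0.66, SE 0.07, adjusted p = 6.62e-14), KCNH2, a repolarizing potassium channel, by 0.90, and SLC8A1, the sodium-calcium exchanger, by 0.35. With the length and GC trend removed the list had camera adjusted p = 0.0668 and SLC8A1 did not pass, nor did it with DESeq2 or without siHoxa5 library 2 or siN library 2.

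Cardiac transcription factors were higher as a group (11 tested, median 0.13, camera adjusted p = 0.0131; adjusted p = 0.201 with an estimated correlation): 4 rose, none fell and 7 did not pass, and adjusted over the list alone 5 rose. Besides PPARGC1A these were MEF2C (331 ± 30.6 to 428 ± 32.6 CPM, 0.37), PROX1 (0.78) and ESRRG, an estrogen-related receptor of energy metabolism (0.30, adjusted p = 0.0496). ESRRG lost its call under most alternatives, PROX1 with DESeq2 and without siN library 1. Nuclear genes of oxidative phosphorylation had a median of 0.19 over 6 tested members (camera adjusted p = 0.0337; adjusted p = 0.201 with an estimated correlation): ATP5F1B, the beta subunit of ATP synthase, rose by 0.32 and NDUFS1, of complex I, by 0.41, while ATP5MC3 (0.14) and ATP5MC1 (0.23) were among the 4 that did not pass; adjusted over the list alone 4 rose. NDUFS1 lost its call with DESeq2 and without siHoxa5 library 2 or 3 or siN library 2 or 4, and ATP5F1B (0.24) without siHoxa5 libraries 2 and 4. Without siN library 1 the camera calls of the hypertrophy marker, calcium handling, transcription factor, oxidative phosphorylation, cytoskeleton and proteasome lists were lost.

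Genes of the unfolded protein and integrated stress response were lower as a group (8 tested, median -0.31, camera adjusted p = 0.0178; adjusted p = 0.201 with an estimated correlation). HSPA5, the endoplasmic reticulum chaperone BiP, went from 1168 ± 34.0 to 917 ± 23.6 CPM (-0.35, SE 0.06), the only member of the 8 that fell, and none rose; adjusted over the list alone 3 fell. HSP90B1 had -0.31, HYOU1 -0.50 and XBP1 -0.33, none past the threshold over all genes. With every gene that had a count included, the median was 0.04 and the call ended. Immediate-early and MAPK-responsive genes, which report recent growth-factor or stress signalling, were lower as a group (12 tested, median -0.18, camera adjusted p = 0.0113; adjusted p = 0.201 with an estimated correlation), although none of the 12 passed alone, also when adjusted over the list alone. The largest values in it were those of NR4A1 (-0.77, SE 0.33), EGR3 (-0.74, SE 0.30), EGR2 (-0.61, SE 0.25) and DUSP5 (-0.47, SE 0.17).

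Cytosolic ribosomal protein genes were lower (24 of 86 listed genes tested, median -0.19, camera adjusted p = 0.00805; adjusted p = 0.307 with an estimated correlation): 6 fell, none rose and 18 did not pass, and 12 fell adjusted over the list alone. Examples are RPLP0 (11206 ± 304 to 9737 ± 1086 CPM, -0.20), RPL31 (-0.24), RPL37 (-0.22) and RPL29 (-0.28), of which RPL29 and RPL37 were not called with DESeq2, nor RPLP0 without siN library 1. Reads of these genes can be shared with pseudogenes. With every gene that had a count included, the list's median was 0.11 and the call ended; with the length and GC trend removed the median was -0.08 and the call ended. Ubiquitin-proteasome and atrophy genes had a median of -0.20 over 8 members (camera adjusted p = 0.0178; adjusted p = 0.201 with an estimated correlation), with none past the threshold over all genes and 2 lower adjusted over the list alone. USP14 had -0.32 (SE 0.11), PSMC4 -0.45 (SE 0.17), PSMD11 -0.17 and PSMD1 -0.12. Removing the length and GC trend ended that call too (median -0.14).

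Genes of cardiomyocyte dedifferentiation and the cytoskeleton had a median of -0.14 over 12 members (camera adjusted p = 0.0494; adjusted p = 0.282 with an estimated correlation). Of the 12, 3 fell, none rose and 9 did not pass; adjusted over the list alone 5 fell. ACTN1, the non-muscle alpha-actinin, went from 2302 ± 7.42 to 1737 ± 170 CPM (-0.40), TUBB6, a beta-tubulin, had -0.34 and TAGLN2 -0.49; RUNX1, with -0.47 (SE 0.16, adjusted p = 0.0508), did not pass, but did with limma-voom and without siHoxa5 library 1 or 3. The list's call was at the threshold and was lost under most alternatives.

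**Figure D3:**
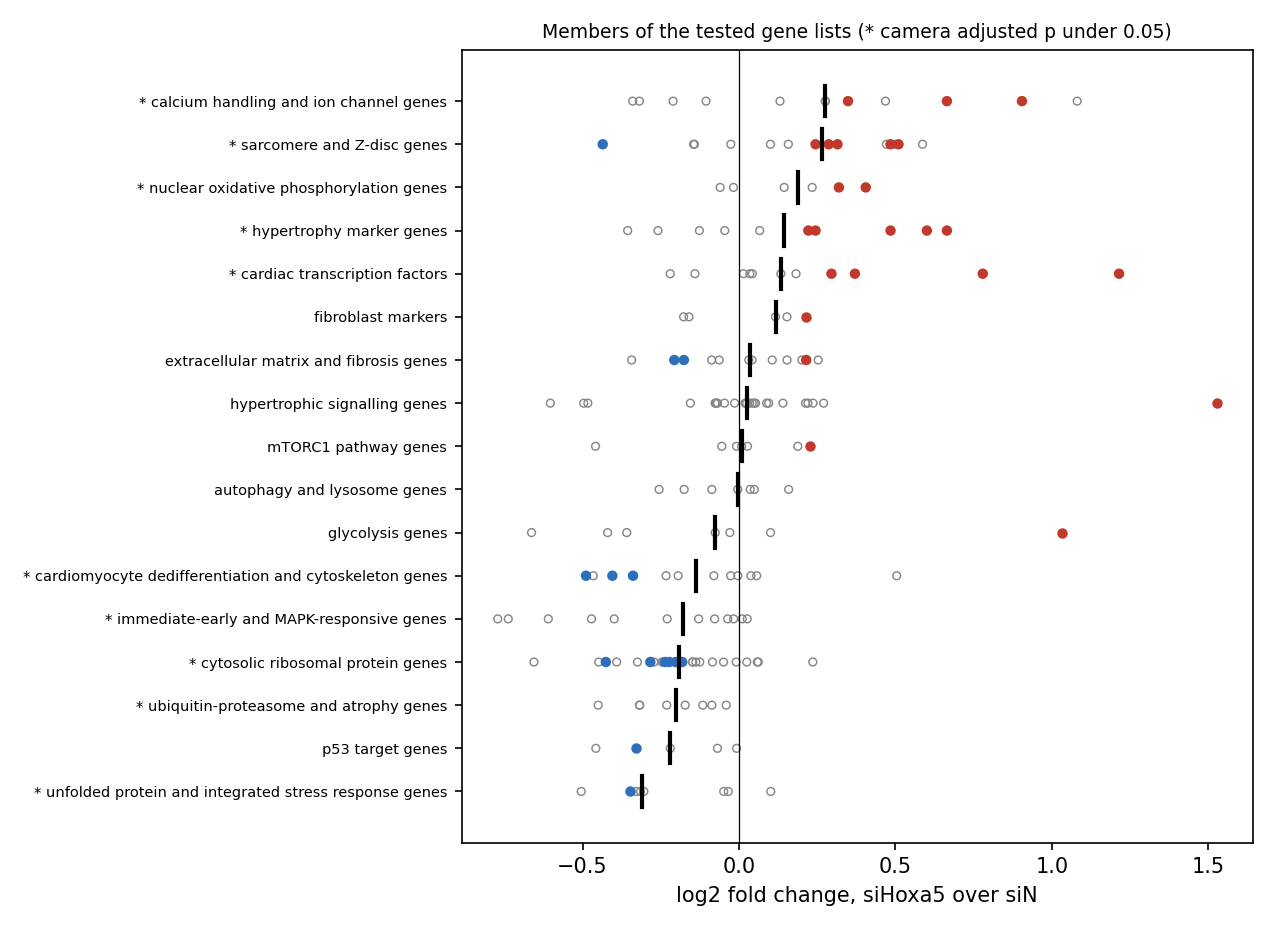
Log2 fold changes (siHoxa5 over siN, horizontal axis) of the tested members of 17 gene lists (rows). Filled points are genes at adjusted p under 0.05 (red higher, blue lower), open points the others, and black bars list medians, from 0.28 for calcium handling and ion channel genes to -0.31 for the unfolded protein and integrated stress response genes.

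In sum 10 of the 17 tested lists passed camera with the preset correlation, 5 higher and 5 lower. With an estimated correlation 0 passed, and 3 had an unadjusted p under 0.05 (immediate-early, unfolded protein response and sarcomere genes); fry called 9. With all genes that had a count included 4 lists passed, without siN library 1 also 4, and without siHoxa5 libraries 2 and 4 again 4, of which 1 was higher and 3 lower. Of the 5 higher lists only the sarcomere list kept its call without those 2 libraries; the hypertrophy marker, calcium handling, transcription factor and oxidative phosphorylation lists lost theirs, as did the lower cytoskeleton and proteasome lists. The log2 fold changes of tested genes had a Spearman correlation of 0.215 with transcript length across genes, which are not independent replicates. With that trend and the one on GC content removed, 6 of the 10 lists still passed: sarcomere, hypertrophy marker, transcription factor, oxidative phosphorylation, immediate-early and unfolded protein response genes.

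The other 7 tested lists did not pass. Of 25 hypertrophic signalling genes HDAC9 alone rose and none fell (median 0.02, camera adjusted p = 0.738); ADRA1B, an alpha1-adrenergic receptor, had -0.48 (SE 0.21, adjusted p = 0.159; -0.80 and past the threshold without siHoxa5 libraries 2 and 4), AKT1 0.21 and CAMK2B -0.60. Of 7 glycolysis genes PFKM rose, while ENO3 (-0.66), PGAM1 (-0.42) and SLC2A1 (-0.36) did not pass (median -0.08, adjusted p = 0.444; 1 rose and 1 fell adjusted over the list alone). Extracellular matrix and fibrosis genes went both ways: of 12, COL1A1, type I collagen, rose by 0.21 (8861 ± 166 to 10284 ± 725 CPM), while SPARC (-0.21) and FN1, fibronectin (-0.18), fell, and THBS1 (-0.34) was among the 9 that did not pass. That list's median (0.04) and mean (0.01) were above 0 and camera's direction was down (adjusted p = 0.868); 1 rose and 3 fell adjusted over the list alone. Among 5 p53 target genes PHLDA3 fell by 0.33, GADD45A had -0.46, PLK2 -0.22 and SESN1 -0.07 (median -0.22, adjusted p = 0.0515; 2 fell adjusted over the list alone). Among 7 mTORC1 pathway genes RPS6KB1 rose by 0.23; RRAGC had -0.46, MTOR 0.19 and EIF4E 0.03 (median 0.01, mean -0.01, camera direction up, adjusted p = 0.845). FN1 and RPS6KB1 lost their calls with DESeq2 and in most fits without 1 library. None of 7 autophagy and lysosome genes passed, with GABARAPL2 at -0.26, MAP1LC3A at 0.16, BECN1 at -0.09 and GABARAPL1 at -0.18 (median -0.00400, adjusted p = 0.845).

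Lists with fewer than 5 tested members were not tested as groups. AIFM1, a mitochondrial flavoprotein of the apoptosis list, rose by 0.31, with MCL1 at -0.35, XIAP at 0.32 and BCL2 at -0.11. TOP2A, a topoisomerase of dividing cells, rose by 0.44, with MCM4 at 0.61 and CCNA2 at 0.26 not past the threshold. AIFM1 was not called with DESeq2 or without siHoxa5 library 1, 3 or 4 or siN library 1, 2 or 3, and TOP2A not with DESeq2 or without siHoxa5 library 1 or 3 or any siN library. No member passed over all genes among fatty acid oxidation genes (ETFA 0.24, ETFDH 0.38, HADHB 0.23), antioxidant genes (GCLM 0.40, PRDX1 -0.12, GCLC -0.26) or NF-kB and cytokine genes (SOCS3 0.23, NFKBIA -0.06). Adjusted over the list alone, 1 fatty acid oxidation gene rose, and no antioxidant or NF-kB and cytokine gene passed. The mitochondrially encoded MT-CO1 had 1.44 (SE 0.57, adjusted p = 0.215); it passed with DESeq2, limma-voom and edgeR without robust estimation. No interferon-stimulated gene passed the expression filter, so an interferon response to transfected RNA could not be assessed.

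Markers of other heart cells were compared because isolated cardiomyocytes can carry such cells. Fibroblast markers made up 1.11% ± 0.0311 of counts in siN and 1.246% ± 0.0828 in siHoxa5 (SD, n = 4 each, exact permutation p = 0.0571, adjusted p = 0.571), mostly from COL1A1. The list's 5 tested members had a median of 0.12 (camera adjusted p = 0.845), with LAMC1 at -0.18, COL1A2 at 0.15 (0.33 and past the threshold without siHoxa5 libraries 2 and 4) and FBLN1 at -0.16. Endothelial markers held 0.00452% of counts in siN against 0.00343% in siHoxa5, mesothelial markers 0.00689% against 0.00607%, Schwann and neuronal markers 0.00553% against 0.00538%, smooth muscle and pericyte markers 0.00228% against 0.00250% and atrial cardiomyocyte markers 0.00403% against 0.00424%. Macrophage markers held 3.91e-05% against 0.000129%, lymphocyte markers 0% against 4.46e-05%, and erythroid and adipocyte markers had no counts. None of the 10 shares differed at an adjusted or unadjusted exact permutation p under 0.05. An adjusted p under 0.05 was nearly out of reach, as most of the shares would need the smallest p that 4 against 4 allows. Of 18 markers listed for each type, 12 fibroblast, 5 endothelial and 4 macrophage markers had any count. A difference in other heart cells could thus be missed. Single tested markers were ENG (-0.65, endothelial), MYH11 (0.08, smooth muscle), GPM6A (-0.39) and WT1 (-0.17, mesothelial), MBP (0.20, Schwann) and STARD10 (-0.10, atrial), none past the threshold.

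The groups also differed in library properties. The siHoxa5 libraries had lower totals (exact permutation p = 0.0286, adjusted p = 0.0571, the smallest p that 4 against 4 allows), and the 10 most counted genes held a larger share, 16.8% ± 0.542 against 15.4% ± 0.104 (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.0571). Those 10 include MYH7, MYH6, TPM1 and COL1A1, called higher in siHoxa5, and RPLP0, called lower. Their share is thus not separate from the changes of single genes. Genes detected were 5510.5 ± 182 against 5361 ± 46.4 (exact permutation p = 0.114). Mitochondrially encoded mRNAs held 0.0154% ± 0.00926 of counts in siHoxa5 and 0.00461% ± 0.00248 in siN (exact permutation p = 0.0571, adjusted p = 0.0762), with siHoxa5 library 1 (0.00455%) inside the range of the siN libraries. By the adjusted p 0 of 4 properties differed and by the unadjusted p 2 did; without siHoxa5 library 1 all 4 did. The siN libraries were close to each other (Pearson correlations of log2 CPM 0.979 to 0.981), the siHoxa5 libraries less so (0.973 to 0.980), and correlations between groups were 0.969 to 0.977.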

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

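Tests of 2 explanations in this part, a trace of human RNA and a trend with transcript length and GC content, were set before their result was seen; the other tests were chosen after it. A library was marked when it lay far from the other 3 of its group by its gap to the nearest over the range. Chance marks about 1 in 20 groups, 12.2 of the 243 groups compared, and 14 were marked, with no library holding more than 3. In siN libraries the marked values were MSN at 1766 CPM in library 3 (others 1889 to 1913), PSMD1 at 603 CPM in library 1 (others 519 to 532) and ENG at 23.8 CPM in library 2 (others 19.9 to 20.5). In siHoxa5 libraries they were CAMK2B at 10.9 CPM in library 2 (others 19.57 to 20.01), MEF2C at 379.9 CPM in library 3 (others 439 to 451), XBP1 at 13.1 CPM in library 1 (others 36.4 to 40.8), and, in library 4, PGAM1 at 34.6 CPM (others 40.8 to 41.9), GADD45A at 50.9 CPM (others 65.2 to 66.9) and MCL1 at 41.8 CPM (others 57.1 to 60.1). Of library properties, the mitochondrial share in siN library 3 was 0.00829% (others 0.00299% to 0.00380%) and the share of the 10 most counted genes in siN library 1 was 15.2% (others 15.4%). Macrophage marker shares of 0.000156% in siN library 3 and 0% in siHoxa5 library 3, and a lymphocyte marker share of 0.000179% in siHoxa5 library 2, each rest on 1 count or none.

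The first pattern weighed is the low total with abundant heart genes at 0. Shallow sequencing leaves the shares of genes as they are, and 48 of 75 fatty acid oxidation and oxidative phosphorylation genes at 0 in all libraries argue against it as the whole cause, as does the low mitochondrial share. RNA of human cells would bring mitochondrial mRNAs at 1% or more, and their share was at most 0.0264%. Mouse reads counted against a human annotation, where only stretches of near-identical sequence draw counts, is a candidate explanation. The rows include LINC rows, human intergenic RNAs, and many symbols without a mouse namesake, so the row names are those of a human annotation. Whether the reads were also aligned to a human genome stays open, and so does how much of each mouse transcript a row counts. LINC rows held 0.00539% of all counts, and abundant transcripts such as FTH1 (3 counts in all), B2M (4) and MALAT1 (4) were nearly absent. The submitters' notes name mm10, no human genome was used here, and, as the pattern is in all 8 libraries, no biological explanation was tested.

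The second pattern is the higher mitochondrial share and number of genes detected in siHoxa5 libraries 2, 3 and 4. Smaller libraries do not account for it, since with equal numbers of counts drawn these libraries still detected at least 5407 genes, against 5218 to 5319 in siN. A trace of human RNA predicted a higher share of counts in rows without a mouse namesake; the lowest of the 3 libraries had 0.611%, inside the siN range of 0.610% to 0.625%, and their mean was 0.615% against 0.617% in siN, which argues against a trace that adds as much to these rows as to mitochondrial mRNAs (0.0144%). A smaller addition stays open, and the bound set beforehand was wrong to ask for a rise above every siN library: the share of human RNA that falls in these rows is in no table, and in the rows with few counts the 3 libraries held 0.0527% to 0.0572%, against 0.0492% to 0.0560% in siN. A rise of mitochondrial transcripts with the Hoxa5 siRNA stays open too, as 1 of the 4 siHoxa5 libraries lay within the siN range. The summed counts of 8 abundant transcripts of other origin were also higher (2, 6, 3 and 0 in siN libraries, 6, 7, 8 and 14 in siHoxa5 libraries), which goes against it. Of these counts FTL alone held 21, and PSAP went the other way (2 in siN library 3, 0 in every siHoxa5 library). A trace of human RNA and a rise of mitochondrial transcripts cannot be told apart with so few counts.

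The third pattern is that lists of contractile and calcium handling genes were higher, and lists of cytoskeletal, chaperone and proteasome genes lower, by camera with the preset correlation, though most members did not pass alone and 0 lists passed with an estimated correlation. A trend with length and GC content of the longest mouse transcript was removed, and 6 of the 10 lists still passed. Of this pattern the sarcomere and unfolded protein response lists kept their calls, and the calcium handling, cytoskeleton and proteasome lists did not. For lists that kept their calls, the trend on the longest mouse transcript did not account for the whole call at the preset correlation. The camera adjusted p was then 0.00838 for the sarcomere and 0.0450 for the unfolded protein response list. The length of the stretches that drew counts is not known, so a trend with that length stays open for these lists too. For the sarcomere list, reads shared between myosin heavy chains cannot be the whole cause of the call, as it passed without them (median 0.22, camera adjusted p = 0.0406). For the hypertrophy list these reads stay open, as its median was 0.0111 without them and its call ended. For the 4 lists that lost their calls the trend stays open. Their medians moved from -0.19 (SD 0.19 over genes) to -0.08 (0.20) for ribosomal proteins and from -0.14 (0.28) to -0.08 (0.29) for cytoskeleton. They moved from -0.20 (0.14) to -0.14 (0.15) for proteasome and from 0.28 (0.46) to 0.20 (0.46) for calcium handling genes, a share left of 0.424 to 0.713. The calls ended with the smaller medians, since the same genes with the trend left in gave all 10 calls. Among the 6 that passed, medians also shrank for sarcomere (0.27 to 0.19), transcription factor (0.13 to 0.09), immediate-early (-0.18 to -0.12) and unfolded protein response genes (-0.31 to -0.28). They grew for hypertrophy marker (0.14 to 0.16) and oxidative phosphorylation genes (0.19 to 0.25). Whether a list kept its call thus did not follow from the move of its median alone. List and length go together, so the 2 cannot be told apart. Fewer other heart cells in the siHoxa5 libraries stay open: fibroblast markers held 0.138 percentage points more, nearly all from COL1A1, and 0.00998 more without it (SD 0.0186 in siN, 0.0368 in siHoxa5), while endothelial and mesothelial shares were lower. An effect of the Hoxa5 siRNA is 1 of the open explanations for the 10 lists, with off-target effects of the siRNA untested and no reduction of HOXA5 measured.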

How the results depend on the processing

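Alternatives that left out siHoxa5 libraries 2 and 4, removed the myosin heavy chain genes, thinned the libraries or removed the length and GC trend were chosen after the result was seen. The 215 genes became 112 with DESeq2, 111 at an adjusted p under 0.01, 15 at a log2 fold change of at least 1 in size as well, 143 without siHoxa5 libraries 2 and 4, and 145 to 260 with any 1 library left out, with no change of sign. Lists past the threshold, 10 as reported, numbered 0 with an estimated correlation (3 at an unadjusted camera p under 0.05), 4 with every gene that had a count (3 of them among the 10), 6 with at least 1 CPM in 4 libraries (5 among the 10), 4 without siHoxa5 libraries 2 and 4, 6 with the length and GC trend removed, and 4 to 10 with 1 library left out. Library properties past the threshold were 0 to 4 with 1 library left out, and marker shares 0, which says nothing of stability because 6 of the 10 shares would need the smallest possible p to pass. The difference in HOXA5 ranged from -0.264 to 1.502 CPM, so its sign rested on single libraries.

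With a term for the replicate number 250 genes (125 higher, 125 lower) and 7 lists were called, and all 215 genes were among the 250. Correlations of deviations were 0.0869, 0.0379, 0.0107 and 0.0730 for libraries with the same number (1431 genes). For libraries with different numbers they were -0.0908 to 0.0550. Values this small cannot tell whether the numbers pair the groups, and the main fit left the number out. The cause of the larger count of genes was not tested.

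Signs turned only for results that had not passed, except the ribosomal protein median, which was 0.11 with every gene that had a count. A list median counts as turned when camera's direction did. The unfolded protein response median, above 0 with every gene that had a count, is left out for that reason. Without siHoxa5 libraries 2 and 4 the turned values were BECN1 0.0135, EIF4E -0.10, FBLN1 0.11, HADHB -0.13, PRDX1 0.13, and medians of hypertrophic signalling -0.0382, mTORC1 -0.10 and extracellular matrix 0.10 (0.0321 with the replicate term). With the trend removed they were EIF4E -0.00492, NFKBIA 0.0297, and medians of autophagy 0.0263 and fibroblast markers 0.0576; in thinned libraries BCL2 0.0204, NFKBIA 0.0104 and mTORC1 0.0255; with limma-voom STARD10 0.0205. The mTORC1 median was 0.00549 with at least 1 CPM in 4 libraries and 0.0276 with every gene that had a count.

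With 1 library left out, log2 fold changes ranged for BCL2 from -0.29 to 0.0889, EIF4E -0.0371 to 0.0774, MBP -0.0282 to 0.38, MYH11 -0.14 to 0.38, NFKBIA -0.18 to 0.0728, SESN1 -0.37 to 0.17 and STARD10 -0.34 to 0.25. Medians ranged for autophagy from -0.11 to 0.11, extracellular matrix -0.0258 to 0.16, fibroblast markers 0.00929 to 0.22 and mTORC1 -0.0768 to 0.0803. Differences in marker shares ranged for Schwann and neuronal markers from -0.000367 to 0.000143 points, atrial -0.000279 to 0.000606 and smooth muscle -0.000165 to 0.000642.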

Other observations

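The genes named in this part were chosen after their values were seen, and the split of the samples was the only test set before its result. Several genes that serve secretory transport, which no list fixed beforehand covered, were among the genes called lower. Their families were then gathered by name (coat, SEC, ARF, ARL, RAB, TMED, PDIA, SSR, RPN and SRP families). Of 49 tested, 12 fell, none rose and 37 did not pass, and 44 had a negative log2 fold change (median -0.17, SD 0.21 over genes). Without the 12, whose calls prompted the choice in part, 32 of 37 were negative and the median was -0.12. Those that fell include SRPRA, a receptor for the signal recognition particle (-0.29), COPB1 and COPB2, subunits of the COPI coat (-0.31 and -0.40), SEC23A of the COPII coat (-0.45), the GTPases ARF1 (-0.36), ARF6 (-0.17), ARL1 (-0.56), RAB21 (-0.25) and RAB30 (-0.41), and RPN2, which takes part in N-glycosylation (-0.39). Because the set was chosen from these data, no test of it is given.

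The myosin heavy chain genes MYH3 and MYH13, chosen after their values were seen and not usual in adult heart, had log2 fold changes of 0.99 and 0.94, where reads of MYH6 or MYH7 counted under those symbols cannot be excluded.

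The 8 libraries can be split into 4 and 4 in 35 ways. The real split gave 215 genes and the highest other split 2, so 1 of 35 splits reached the real value. That is the smallest share this test can give, and it does not exclude chance assignment. All other splits mix the groups, so a group difference of any origin keeps their counts low. For gene lists the real split gave 10 and the highest other 4, again 1 of 35.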
